A study of Mus musculus with 6 samples.

How the data were processed

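RNA from mouse olfactory epithelium was analysed in 6 libraries, 4 from E18.5 and 2 from postnatal day 21, with 1 library per genotype. Per the labels' protocols, polyadenylated RNA was made into libraries with the ScriptSeq V2 kit, and the animals had a mixed background, chiefly C57/B6. Per the submitters' processing notes, TopHat, Cufflinks and Cuffdiff were used with the mouse build mm9. Their versions and the gene annotation are not given in the sources used here. The authors deposited FPKM, fragments scaled by transcript length and by mapped fragments, for each gene symbol. Per the file headers, the embryonic table also holds the lower and upper bounds of a confidence interval for each FPKM; its level is not given in the sources used here, and with 1 library it rests on the tool's model of the variance. Some FPKM lay outside their own interval (256 to 330 genes per library). Per the file headers, the postnatal table holds p-values and q-values of the authors' test of 1 library against 1 library, which compares the libraries and not the genotypes. The tables were made separately, so comparisons were made only within a table. Among its symbols, 25 in the postnatal table had been turned into dates and carry no gene name. Coordinates are those of the deposited tables on mm9, written from 1.

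All groups came from the labels. The comparisons were G9a/GLP dKO, G9a KO and G9a KO GLP het, each against G9a het, and Suv420h dKO against Suv420h dhet. The 3 embryonic comparisons share the G9a het library, so chance values of that library enter all of them. No test between groups was run, because no group had replicates; random lists of genes and random sets of receptors describe single pairs of libraries. Ratios are on log2(FPKM + 1), or log2(FPKM + 0.1) for Olfr genes, which understates the differences of low genes. Genes other than receptors entered with 1 FPKM or more in either library, and receptors with 0.5 FPKM or more. Genes at least 2-fold apart were counted. Symbols starting with Mir, Snor, Rnu, Scarna or n-R were left out, because FPKM of very short RNAs is unstable. A value of 0 can be a failed estimate: 2 to 9 genes in 3 of the embryonic libraries were at 0 with 10 FPKM or more in every other library. No fold is given against 0. Receptors share sequence, and how reads with several matches were assigned is not given in the sources used here, so values of receptors with a close copy are uncertain.

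For 34 gene lists with 635 entries, the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart when at least 5 members were measured and its median lay outside the central 95% of random lists. This describes these libraries and is not a p-value. The lists, thresholds, comparisons and main alternatives were fixed before the data were examined. Named genes followed a rule fixed at the same time. It took the targeted genes; the 10 highest and 10 lowest ratios among genes at 5 FPKM or more (3 and 3 for the G9a KO and G9a KO GLP het comparisons); the 5 most abundant receptors of each library; the 5 highest and 5 lowest receptor ratios of the main comparisons; and up to 4 members of each described list. Predicted and unnamed loci were left out of the ratio ranks. Other names were chosen after their values were seen: the neighbours of the top receptors, the enamel and cornified skin genes not covered by the rule, Foxf1a and Serpina3n.

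Total depth was not given. In the low values of Olfr genes with a span under 1100 bp, FPKM times length falls in steps of 1 fragment. The step size was taken as the largest local peak within 5% of the best score of a periodogram, a rule set after the data were examined and tested on simulated data, where it recovered 8 of 8 step sizes within 5%; earlier forms of the rule failed there, so this is not an independent check. The worth of 1 fragment was 0.0760, 0.0758, 0.156 and 0.0980 FPKM times kb in the embryonic libraries in the order G9a het, G9a KO, G9a KO GLP het and G9a/GLP dKO, and 0.0624 and 0.0758 in the postnatal ones. Embryonic steps were blurred, so those fragment numbers are estimates. Receptor fragments were drawn down 100 times. Counting error was simulated 100 times from shares common to both libraries, with each library keeping its own receptor total. Simulated counts of higher and lower receptors therefore also hold the difference in totals. Of errors, the draws and simulations cover counting error only, since fragments without molecular identifiers are not independent molecules. In simulated lists of 15 genes over 14699 genes, 10 of 200 lists with no shift and 100 of 100 lists shifted by 0.5 on the log2 scale stood apart.

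Receptor similarity was measured with blastn 2.17.0 between the longest open reading frames (600 nt or more) of GENCODE M21 transcripts matched by symbol, with at least 80% of the frame aligned; no coordinates were taken from that annotation. A sequence was found for 1101 of 1119 receptors. Genome grouping was described with 100000 random sets of receptors. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered the pseudocount, the minimum, the fold threshold, the detection limit, 3 rescalings, the authors' status flags, pseudogenes, the top receptor, the bins and the reference library. Sheets of the postnatal workbook that repeat the receptor rows were not used.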

Results

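Polyadenylated RNA was sequenced from mouse olfactory epithelium, the nasal tissue whose sensory neurons each express chiefly one of the olfactory receptor (Olfr) genes. The study asked about enzymes that place repressive histone marks: G9a (Ehmt2) and GLP (Ehmt1), which methylate histone H3 at lysine 9, and Suv420h1 and Suv420h2, which methylate histone H4 at lysine 20. At E18.5, late in embryonic development, 4 libraries were labelled G9a het, G9a KO, G9a KO GLP het and G9a/GLP dKO. At postnatal day 21, 2 libraries were labelled Suv420h dhet and Suv420h dKO. Each genotype had 1 library, so there was no replicate error. Differences below compare libraries, not genotypes, and no p-value of their own is given. Values are FPKM as deposited, and total depth was not given; low receptor values fell in steps that allowed the number of receptor fragments to be estimated, at 6905, 3569, 1523 and 4185 for the 4 embryonic libraries in the order above and at 29678 and 28978 for the postnatal pair. The steps were less sharp in the embryonic table, with scores of 0.144 to 0.218 against 0.713 and 0.806 in the postnatal one, where 1 is a perfect fit.

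The targeted genes were at levels close to those of the reference libraries in the libraries labelled as knockouts, some slightly higher and some slightly lower. Ehmt2 (mm9 chromosome 17, 35035444 to 35050992) was at 24.5 FPKM in G9a het, 30.2 in G9a KO, 32.5 in G9a KO GLP het and 30.4 in G9a/GLP dKO. Ehmt1 (chromosome 2, 24646294 to 24775110) was at 17.3, 20.8, 15.8 and 16.0 FPKM in the same order. The authors' confidence intervals of these values overlapped, for example 17.5 to 31.6 for Ehmt2 in G9a het and 22.0 to 38.8 in the dKO. Suv420h1 was at 31.0 FPKM in the Suv420h dhet library and 30.6 in the dKO, and Suv420h2 at 7.92 and 7.35. The labels do not say which part of each gene was deleted, and gene-level FPKM counts transcript from outside a deleted part. These values therefore neither check the labels nor contradict them, and libraries are named below by their labels.

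The embryonic library labelled G9a/GLP dKO had fewer receptors detected than the G9a het library, and a few receptors held much of its receptor RNA. At 0.5 FPKM or more, 427 of 1119 Olfr genes were detected in G9a het, 154 in G9a KO, 167 in G9a KO GLP het and 89 in the dKO. Summed Olfr FPKM was 632 in G9a het and 443 in the dKO, a ratio of 0.701, which turned to 1.30 when both were divided by the geometric mean of mature olfactory neuron markers (16.1 and 8.72 FPKM). The effective number of receptors, the exponential of the Shannon entropy of their shares, was 641 in G9a het, 274 in G9a KO, 213 in G9a KO GLP het and 39.2 in the dKO. The 5 highest receptors held 3.64% of Olfr FPKM in G9a het, 13.3% in each of G9a KO and G9a KO GLP het, and 43.3% in the dKO. Of the 5 dKO values, those of Olfr231, Olfr878 and Olfr1361 lay above the authors' own intervals, so that share rests partly on uncertain values.

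**Figure D1:**
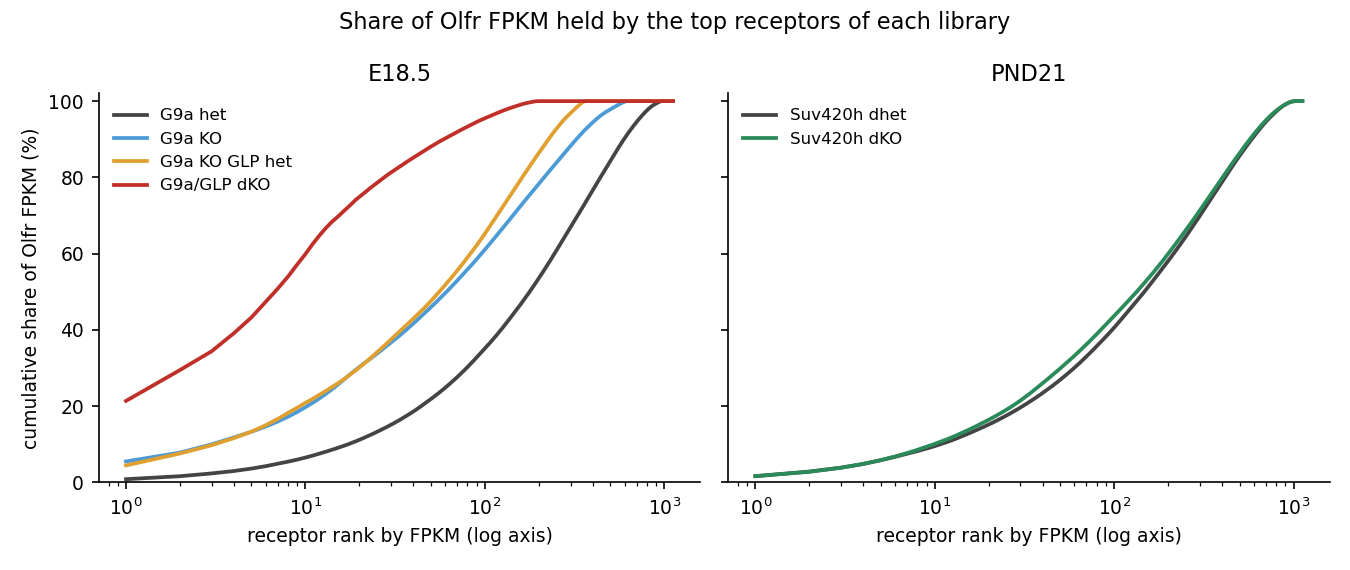
Cumulative share of summed Olfr FPKM (percent, vertical axis) against receptor rank by FPKM (log axis), with 1 line per library, for the embryonic (left) and postnatal (right) libraries. The top receptor held 21.4% of Olfr FPKM in the G9a/GLP dKO library and 0.852% in G9a het, while the postnatal lines lie close together, at 1.63% and 1.66%.

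Of 465 receptors at 0.5 FPKM or more in either library, 49 were at least 2-fold higher in the dKO than in G9a het, 385 at least 2-fold lower and 31 within 2-fold, on log2(FPKM + 0.1). Of the 465, 332 were listed at 0 in the dKO. With the further demand that the authors' intervals did not overlap, 20 were higher and 250 lower. Receptors listed at 0 in the dKO, such as Olfr672, could have an interval of 0 to 0 there. For these the demand rested on the G9a het bound alone. Without that demand, but divided by the mature neuron markers, 81 of 487 were higher and 363 lower. Counting error was simulated for 973 receptors with shares common to both libraries, each library keeping its own receptor total. The simulated counts therefore also hold the difference in receptor totals. They had a mean of 14.0 higher (at most 25) and 59.9 lower (at most 79) over 100 simulations. Among the same 973 receptors, 48 and 325 were observed. Class I receptors were taken as the 124 Olfr genes in the class I cluster of chromosome 7. They held 16.8% of Olfr FPKM in G9a het, 12.2% in G9a KO, 13.8% in G9a KO GLP het and 4.90% in the dKO. A share also falls where other receptors rise. At 0.5 FPKM or more, 68, 22, 23 and 13 class I receptors were detected in that order, against 427, 154, 167 and 89 of all receptors.

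The most abundant receptor of the dKO library was Olfr231 (chromosome 1, 176047222 to 176048145), at 94.6 FPKM against 1.15 in G9a het, 17.1 in G9a KO and 12.1 in G9a KO GLP het. Its dKO value lay above the authors' own interval of 32.3 to 78.1 FPKM, as deposited values of 6 dKO receptors lay outside theirs, and that interval lay above those of the 3 other libraries. Olfr878 (chromosome 9, 37726133 to 37727197) was at 35.9 FPKM in the dKO, above its own interval of 9.25 to 28.3, and at 0.691 in G9a het. Olfr1339 stood at 21.7 against 1.65 FPKM, Olfr464 at 21.1 against 0.962 and Olfr1361 at 18.2 against 1.40. The dKO value of Olfr1361 also lay above its interval, of 4.49 to 16.4 FPKM. Olfr446 was at 18.0 against 0.416 FPKM, Olfr433 at 14.2 (log2 ratio 5.16) and Olfr444 at 8.44 against 0.0786. In the other direction, Olfr672, Olfr523, Olfr969, Olfr640 and Olfr805 had 4.03, 3.55, 3.34, 3.27 and 2.78 FPKM in G9a het and were listed at 0 in the dKO. Olfr15, the highest receptor of G9a het at 5.38 FPKM, was at 0.180 in the dKO, and Olfr578 at 4.60 and 0.321.

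Several receptors that were high in the dKO library were neighbours on the genome. Olfr433 (start 175972064), Olfr231 (176047222), Olfr420 (176088853) and Olfr419 (176180020) lie together on chromosome 1, with Olfr420 at 15.3 and Olfr419 at 11.9 FPKM in the dKO. Olfr448, Olfr446 and Olfr444 lie between 42846452 and 42906431 on chromosome 6. On chromosome 13, Olfr1362 (12.1 FPKM), Olfr11 (3.69 FPKM) and Olfr1361 lie between 21702889 and 21751190. Among the 49 higher receptors, 84 pairs lay within 1 Mb, against a mean of 50.8 in random sets of the same size drawn from the 465 compared. Neighbours were not uniformly higher. Olfr449 on chromosome 6 was at 2.57 FPKM in G9a het and 0.200 in the dKO.

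**Figure D2:**
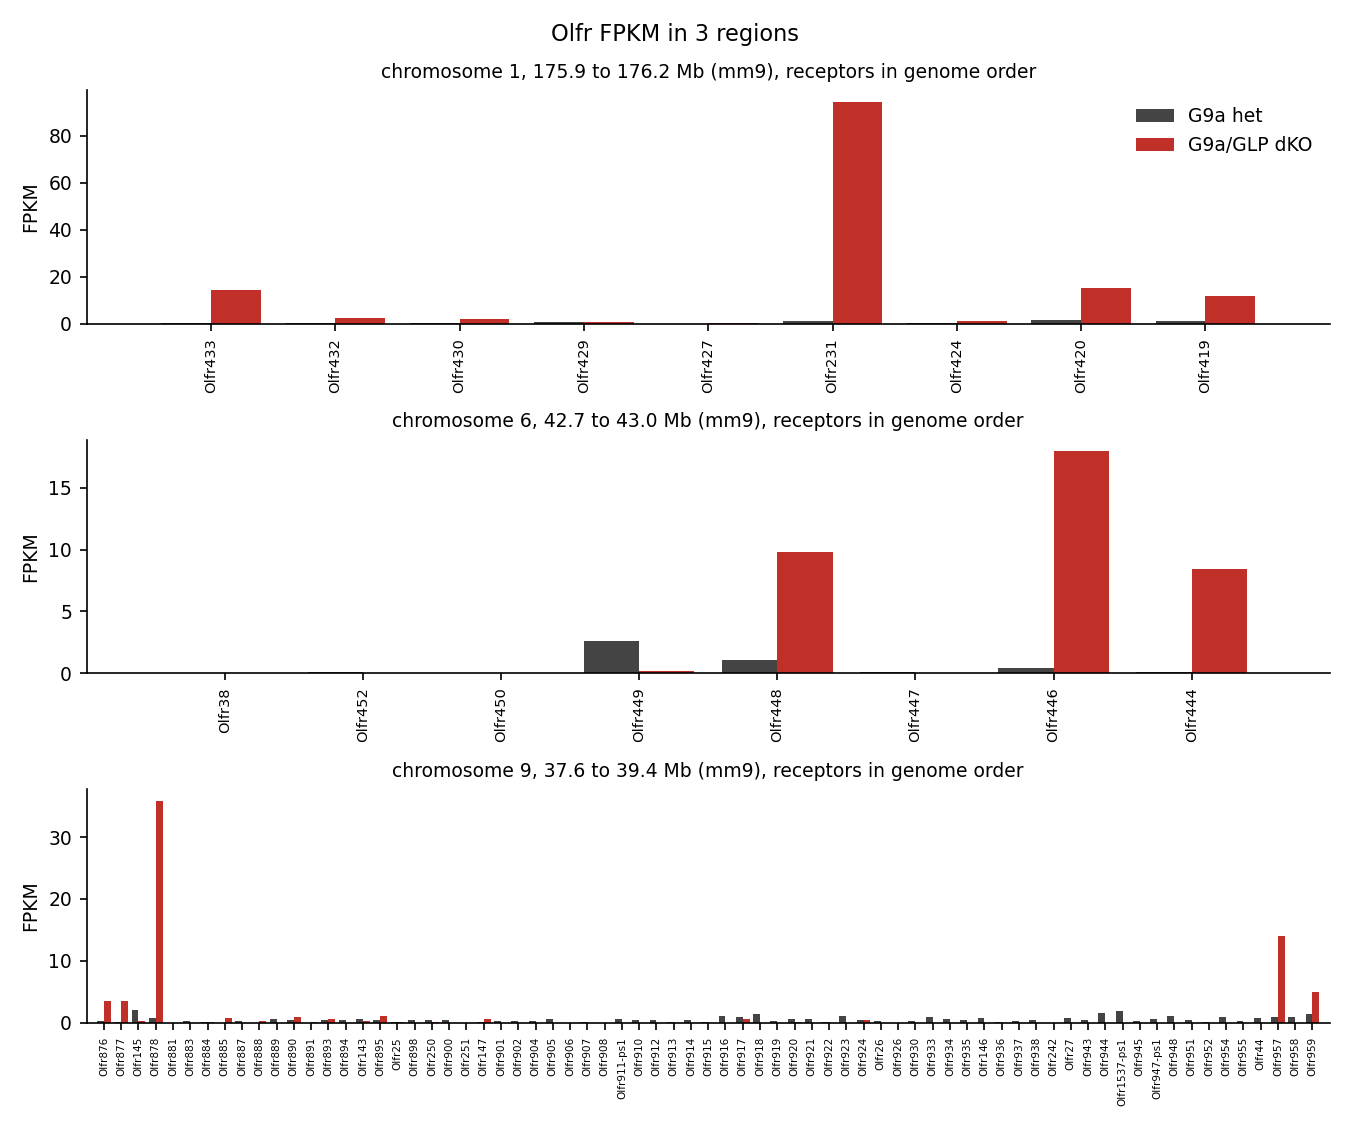
FPKM of every Olfr gene in 3 mm9 regions of chromosomes 1, 6 and 9, in genome order, in the G9a het (grey bars) and G9a/GLP dKO (red bars) libraries; the vertical scales differ and there are no replicates, so there are no error bars. Olfr231 reaches 94.6 FPKM and Olfr878 35.9 FPKM in the dKO library, with Olfr420 at 15.3, Olfr433 at 14.2 and Olfr419 at 11.9 FPKM near Olfr231, while most receptors of the chromosome 9 region are low in both libraries.

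The G9a KO and G9a KO GLP het libraries also had fewer receptors than G9a het. In G9a KO, 44 of 471 receptors were at least 2-fold higher and 309 lower, and the Olfr sum ratio was 0.492, or 0.872 relative to the mature neuron markers. In G9a KO GLP het, 48 of 480 were higher and 317 lower, with a sum ratio of 0.430 that turned to 1.13 relative to the mature neuron markers, whose mean was 6.14 FPKM there and 9.09 in G9a KO. On that scale the split was 106 higher and 239 lower in G9a KO, and 178 and 255 in G9a KO GLP het. Counting error together with the lower receptor totals of these libraries gave up to 179 lower receptors in the first comparison and up to 232 in the second. In each comparison 267 were observed among 973. The same simulations gave at most 4 and 8 higher receptors, against 40 and 42 observed. Lower totals raise the simulated lower counts and reduce the simulated higher ones. Where the authors' intervals were also required not to overlap, 4 were higher and 91 lower in G9a KO. In G9a KO GLP het these counts were 7 and 169. A receptor at 0, such as Olfr640, could have an interval of 0 to 0 here as well. Olfr231 was the highest receptor in both libraries, and Olfr877 reached 7.23 and 8.49 FPKM against 0.162 in G9a het. Olfr510 was at 6.69 FPKM in G9a KO against 1.02 in G9a het, and Olfr549 at 5.70 against 1.87.

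Apart from receptors, the dKO library had lower levels of mature neuron and supporting cell genes than G9a het. All 20 measured mature olfactory neuron markers were lower, with a median log2 ratio of -0.64, and 7 were at least 2-fold lower; with G9a KO as the reference the list no longer stood apart, and with G9a KO GLP het its median was 0.42. Omp, the olfactory marker protein of mature neurons, was at 24.0 against 78.6 FPKM, and Stoml3, a stomatin-like protein of olfactory cilia, at 11.3 against 36.9. Immature neuron genes had a median of 0.00, with Gap43, a growth cone protein, at 89.1 and 92.3 FPKM, and neuronal progenitor genes also had a median of 0.00. Sustentacular (supporting) cell genes had a median of -1.05, with Cyp2f2 at 117 against 318 FPKM and Cbr2 at 239 against 497. Bowman gland and secretory genes had a median of -1.69, with 9 of 13 at least 2-fold lower, including Reg3g at 90.8 against 382 FPKM and Lcn11 at 0.221 against 71.9. Respiratory ciliated genes had a median of -0.56 and microvillar genes of -1.08. Against 10000 random lists matched on expression, each of these medians other than those of immature neurons and progenitors lay below the central 95%. With G9a KO GLP het as the reference the medians were nearer 0, at -0.12 for sustentacular, -0.32 for Bowman gland and -0.15 for ciliated genes. The microvillar list did not stand apart at a minimum of 5 FPKM or with either other embryonic library as the reference.

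Some other lists stood higher in the dKO library. Imprinted genes had a median of 0.30, with 28 of 33 above 0. Dlk1, a Notch-related growth regulator, was at 114 against 48.2 FPKM, and Peg10, a gene derived from a retrotransposon, had a log2 ratio of 1.14. Genes of the G9a/GLP complex and H3K9 methylation had a median of 0.16, with 20 of 28 above 0 and none 2-fold apart. Proliferation genes had a median of 0.22, mesenchyme of 0.30, skeletal muscle of 0.24 and blood of 0.68. Muscle members went both ways, 3 at least 2-fold higher and 2 lower; the muscle list no longer stood apart with no minimum or on the TPM scale, nor the blood list with no minimum. With the G9a KO GLP het library as the reference, the medians of the imprinted, H3K9, proliferation, mesenchyme and muscle lists were below 0, and with G9a KO those of the H3K9, proliferation and blood lists. The blood list includes the alpha globins Hba-a1 and Hba-a2, which share sequence: Hba-a1 was at 0.0205 FPKM in G9a het and 645 in the dKO, while their sum was 1805 and 2112. Cartilage and bone (-0.31), the unfolded protein response (-0.15) and immediate early genes (-0.34) stood lower; the unfolded protein response did not stand apart at a minimum of 5 FPKM or with G9a KO as the reference, and its median and that of immediate early genes were above 0 against G9a KO GLP het.

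**Figure D3:**
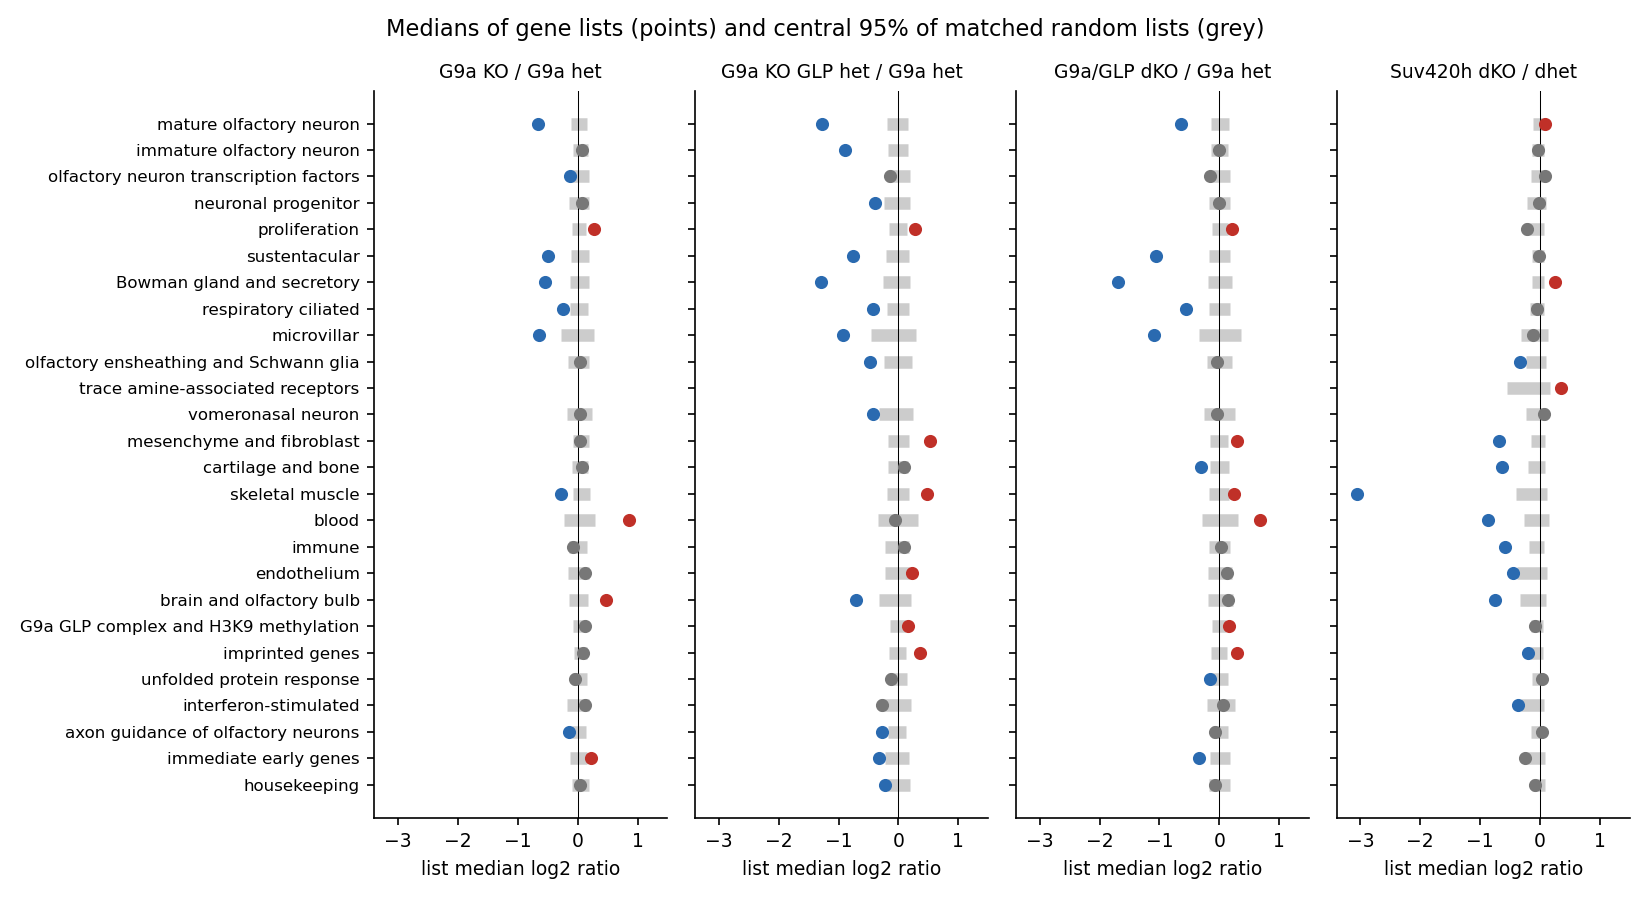
Median log2(FPKM + 1) ratio (horizontal axis) of each gene list that stood apart in at least 1 of the 4 comparisons, the sex-linked list left out; points are list medians, red or blue where outside the central 95% of matched random lists (grey bars). Mature neuron, sustentacular and Bowman gland lists lie to the left in all 3 embryonic comparisons, and skeletal muscle lies at -3.05 in the Suv420h comparison.

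Of 15079 genes other than receptors, 307 were at least 2-fold higher and 304 lower in the dKO library than in G9a het, on log2(FPKM + 1). Some genes of the cornified skin layer were among the highest, including Lce1m at 106 against 1.07 FPKM, Stfa3 at 723 against 28.9 and Krt77, a keratin, with a log2 ratio of 4.09. Some enamel matrix genes were among the lowest, with Amelx at 3.45 against 737 FPKM, Ambn at 4.44 against 141 and Enam at 0.443 against 34.0. In G9a KO and G9a KO GLP het, Amelx was at 388 and 14.6 FPKM, and Lce1m at 3.43 and 80.5. These enamel and skin genes formed no fixed list and were grouped after their values were seen, so the number that differ carries no weight. Cdsn, another cornified skin gene examined, was at 57.6 FPKM in the dKO against 64.4 in G9a het. Tooth or skin tissue taken along was not tested, and with 1 library per genotype it cannot be told apart from genotype. The same limit applies to the cell type lists above. Ttr, a thyroid hormone carrier, was at 1.03 against 65.6 FPKM. Xist, the RNA of the inactive X chromosome, was at 208 against 0.242 FPKM, while the Y-linked Ddx3y was at 33.6 FPKM in G9a het and listed at 0 in the dKO. Xist was also high in G9a KO (140 FPKM), and Ddx3y in G9a KO GLP het (29.2 FPKM), so the sex of the animals differed from that of G9a het in the G9a KO and dKO comparisons and was the same in that of G9a KO GLP het. Zfp266, at 38.1 FPKM in G9a het, was listed at 0 in the dKO, which can be a failed estimate.

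In the G9a KO library, 149 of 14957 other genes were at least 2-fold higher and 152 lower than in G9a het. Mature neuron markers had a median of -0.67, with Omp at 36.0 FPKM, and sustentacular genes of -0.50. Brain and olfactory bulb genes stood higher, with a median of 0.48 and 16 of 17 above 0. Tbr1, a transcription factor of projection neurons, had a log2 ratio of 1.72, and Neurod6, a neuronal transcription factor, was at 24.3 against 7.48. In the G9a KO GLP het library, 318 of 15012 genes were higher and 589 lower. There, mature markers had a median of -1.28 and immature neuron genes of -0.89, with Crmp1 at 7.90 against 33.8 FPKM and Tubb3, a neuronal tubulin, at 31.8 against 95.9. Brain and olfactory bulb genes had a median of -0.70 in this library, and mesenchyme genes of 0.53, with Twist2 at 19.7 against 2.65 FPKM. Among ribosomal protein genes, Rpl26 was at 0.129 against 88.8 FPKM and Rps12 at 242 against 0.599, while the sum over 94 such genes was 11718 against 10148 FPKM.

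Set against all 3 other embryonic libraries at once, the dKO had 21 genes at least 2-fold above each and 19 below. The same counts were 72 and 39 for G9a het, 21 and 15 for G9a KO, and 52 and 190 for G9a KO GLP het. As shares of the 1119 receptors, 0.0322 were above and 0.101 below in the dKO, against 0.223 and 0.0107 in G9a het, 0.0179 and 0.00715 in G9a KO, and 0.0268 and 0.0197 in G9a KO GLP het. Without the G9a KO GLP het library, the dKO had 205 genes apart from both others. Genes outside the naming rule that were apart in the dKO, chosen after their values were seen, include Foxf1a, a mesenchymal transcription factor, at 1.53 FPKM against 10.9 to 14.8 in the others, and Serpina3n at 1.28 against 7.35 to 23.1.

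At postnatal day 21, the libraries labelled Suv420h dhet and Suv420h dKO had similar receptor repertoires. At 0.5 FPKM or more, 821 and 823 of 1118 Olfr genes were detected, and the effective number was 581 and 551. Summed Olfr FPKM was 2352 and 2762, a ratio of 1.17, and 1.13 relative to mature neuron markers. Of 929 receptors compared, 179 were at least 2-fold higher in the dKO, 124 lower and 626 within 2-fold. Counting error, simulated with each library keeping its own receptor total, gave at most 49 higher and 14 lower. Among 972 receptors, 161 and 112 were observed. The most abundant receptors were within 2-fold: Olfr536 was at 38.3 FPKM in the dhet and 45.9 in the dKO, Olfr533 at 23.1 and 31.1, Olfr1507 at 20.9 and 29.4, and Olfr166 at 28.9 and 27.2. Olfr1348 was at 28.5 FPKM in the dKO, a ratio of 1.90, with a q of 0.0414 in the authors' deposited table. Olfr671 and Olfr996, at 2.01 and 1.74 FPKM in the dKO and listed at 0 in the dhet, each had a q of 0.0400 in the authors' deposited table. Olfr1360, with the highest ratio (2.31 against 2.62e-05 FPKM), had a q of 0.999 there. Olfr513 and Olfr1054, also among the 5 highest ratios, had a q of 0.0606 and 0.0722. The 5 lowest ratios had a q between 0.0645 (Olfr410) and 0.335 (Olfr494). The authors' deposited table marked 19 of 900 tested receptors as significant, 18 higher and 1 lower in the dKO.

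**Figure D4:**
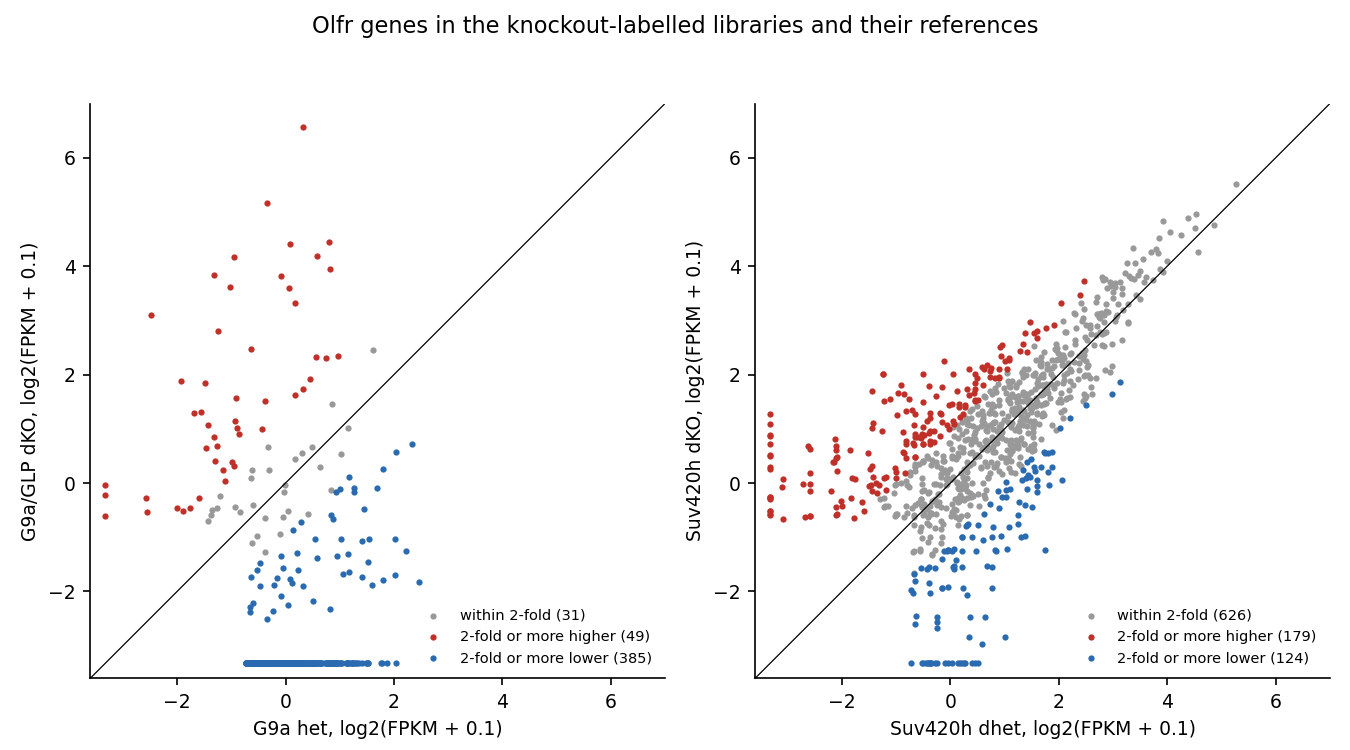
Log2(FPKM + 0.1) of each Olfr gene at 0.5 FPKM or more in either library, for G9a/GLP dKO against G9a het (left) and Suv420h dKO against Suv420h dhet (right); points are genes, the line marks equal values. Of 465 genes on the left 385 are at least 2-fold lower, most of them listed at 0, and of 929 on the right 626 are within 2-fold.

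Skeletal muscle genes differed most between the postnatal libraries. All 14 measured members were lower in the Suv420h dKO, 13 of them at least 2-fold, with a median log2 ratio of -3.05. Mylpf, a myosin light chain, was at 2.42 against 41.1 FPKM. Outside the list, Mb, the oxygen carrier myoglobin, was at 2.31 against 38.5 FPKM. Ckm, the muscle creatine kinase, was at 0.455 against 13.8 FPKM, and Tnnt3, a fast troponin, was listed at 0 in the dKO and at 23.3 FPKM in the dhet. Mesenchyme genes had a median of -0.69, with Col1a1 at 660 against 1858 FPKM, and cartilage and bone genes of -0.63, with Bglap, osteocalcin, at 282 against 1114 FPKM. Immune (-0.59), blood (-0.87), brain and olfactory bulb (-0.75), endothelium (-0.45), interferon-stimulated (-0.37), ensheathing and Schwann glia (-0.34) and imprinted genes (-0.20) also stood lower. The blood list no longer stood apart with no minimum (median 0), on the TPM scale or without the sex chromosomes, nor the imprinted, endothelium and interferon lists at a minimum of 5 FPKM or the glia list without the sex chromosomes. In the authors' deposited table, 14 muscle, 9 mesenchyme and 8 cartilage and bone members were marked significant, all lower in the dKO. Blood members were marked both ways, 2 higher and 3 lower, and 0 of 12 endothelium members were marked.

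Neuronal and supporting cell genes were closer between the postnatal libraries. Mature olfactory neuron markers had a median of 0.08, which was -0.12 after division by the sum of FPKM per library, a scale that moved the median of all genes from -0.06 to -0.24; the list did not stand apart with no minimum, with 50 bins or without the sex chromosomes. Omp was at 1124 FPKM in the dhet and 1108 in the dKO, and no marker was 2-fold apart. Sustentacular genes had a median of -0.01 and did not stand apart. Bowman gland and secretory genes had a median of 0.24, with Muc5ac, a mucin, at 3.50 against 0.433 FPKM and Dmbt1 at 27.3 against 8.69. Trace amine-associated receptors, a small second family of olfactory receptors, had a median of 0.35 over 10 members, and none was marked significant in the authors' deposited table. The highest ratios in the dKO belonged to the lipocalins Lcn3 (243 against 3.96 FPKM) and Lcn4 (151 against 2.96 FPKM). They were followed by the enamel gene Amelx (19.7 FPKM, listed at 0 in the dhet), the chemokine Ccl21a (19.4 against 0.00231 FPKM, with a q of 0.962 in the authors' deposited table) and Crisp1 (137 against 7.12 FPKM). Of 14351 genes other than receptors, 99 were at least 2-fold higher and 296 lower. The authors' deposited table marked 666 of 16140 tested genes as significant, 104 higher and 562 lower, from a test of 1 library against 1 library.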

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

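Interval overlap, sex chromosomes, genes at 0, the drawing down and leaving out G9a KO GLP het were alternatives chosen after seeing the data. With no replicates, counts and values were held the same when within 1.5 times the main value. Of 361 summary values under alternatives, 230 stayed within that limit, 127 moved further and 4 crossed a ratio of 1. Of 1274 list medians, 1222 kept their call, 16 came to stand apart, 23 no longer did and 13 changed sign; of 494 ratios of named genes, 446 kept theirs, 45 were no longer 2-fold and 3 changed sign. The effective number of receptors was recomputed only without the top receptor, without pseudogenes, and with Olfr fragments drawn down, to 1523 in each embryonic library. It stayed within 1.5 times under each of these (440 in G9a het and 32.5 in the dKO when drawn down). The drawn-down values covered only Olfr genes with a span under 1100 bp. The sum of repeated symbols was not run, since no symbol was repeated, and removing the minimum moved no count of genes, because a 2-fold ratio on log2(FPKM + 1) already needs 1 FPKM. Depth limits the low receptors, where 1 fragment of a 1 kb gene is worth 0.0624 to 0.156 FPKM.

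Counts of genes apart are given in the order G9a/GLP dKO, G9a KO, G9a KO GLP het and Suv420h dKO, with main values of 611, 301, 907 and 395, and for the dKO against all 3 other embryonic libraries of 40. They were 1149, 622, 1493, 1007 and 164 with a pseudocount of 0.1, and 200, 83, 270, 66 and 10 with a pseudocount of 5. A minimum of 5 FPKM gave 402, 176, 543, 169 and 26. A 3-fold threshold gave 199, 86, 258 and 76, and intervals apart 343, 161 and 540 in the embryonic comparisons. Fewer genes are counted by construction in these last settings. On the TPM scale they were 1186, 605, 1561, 1040 and 140; FPKM divided by their sum are larger numbers, so the pseudocount and minimum weigh less. This scale moved the median of all genes in the Suv420h comparison from -0.06 to -0.24, so its list medians are to be read against that shift. With G9a KO as the reference the dKO had 358 genes apart, and 205 without the G9a KO GLP het library.

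Receptors higher in the same order had main counts of 49, 44, 48 and 179, and receptors lower of 385, 309, 317 and 124. With a receptor pseudocount of 1 there were 29, 13, 11 and 58 higher and 156, 78, 108 and 35 lower. With detection at 0.1 FPKM, 86 (G9a KO) and 75 (G9a KO GLP het) were higher and 754, 595 and 638 lower in the embryonic comparisons. With detection at 1 FPKM, 23 and 24 were higher in the same pair, and 170, 139, 142 and 80 lower in all 4. On the TPM scale 83 and 73 were higher in that pair, and 680, 584, 574 and 188 lower. With intervals apart, 20, 4 and 7 were higher and 250, 91 and 169 lower. Those lower counts rest on the G9a het bound alone where the other interval was 0 to 0. Relative to mature neuron markers, 81, 106 and 178 were higher. The lower count of the dKO was 104 against G9a KO and 122 against G9a KO GLP het. The Olfr sum ratio of the dKO was 1.42 against G9a KO, 1.63 against G9a KO GLP het and 1.30 per mature neuron marker; per marker it was 0.872 for G9a KO and 1.13 for G9a KO GLP het. The cause was not tested.

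List medians of the dKO changed sign with another reference. Against G9a KO these were proliferation (-0.048), blood (-0.31), H3K9 methylation (-0.0059) and the sex-linked list (0.57). Against G9a KO GLP het they were mature neuron (0.42), proliferation (-0.11), mesenchyme (-0.23), muscle (-0.20), H3K9 methylation (-0.029), imprinted (-0.11), unfolded protein response (0.039) and immediate early genes (0.075). Hba-a1 was at -2.71 against G9a KO, and Ttr at 0.50 and Olfr578 at 0.56 against G9a KO GLP het. The cause was not tested. The mature neuron list of the Suv420h comparison was at -0.12 on the TPM scale, which moved the median of all genes by a like amount.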

Other observations

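Tests chosen only after the result was seen were that of fewer neurons, that of chance placement and both on muscle genes; drawing down fragments was likewise added after the data were seen, with its bound written before its own result. Protocadherin genes, whose promoters are also chosen in single neurons, gave other values that belong to no comparison above. The summed FPKM of the 22 protocadherin beta genes was 49.8 in G9a het, 30.1 in G9a KO, 25.7 in G9a KO GLP het and 28.2 in the G9a/GLP dKO. Mature neuron markers were at 0.564, 0.381 and 0.541 of their G9a het level in the last 3 libraries. Protocadherin alpha genes summed to 22.8, 16.9, 11.4 and 18.6 FPKM in the same order. Protocadherin gamma genes summed to 78.6, 76.0, 82.3 and 96.3 FPKM in the same order. Vomeronasal receptors of the V1R family summed to 22.9, 18.9, 10.6 and 3.83 FPKM, and those of the V2R family to 10.03, 7.89, 6.01 and 11.7. In the postnatal pair, protocadherin beta genes summed to 124 FPKM in the dhet and 125 in the dKO.

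The first pattern was the narrower receptor repertoire of the G9a/GLP dKO library. Drawn down to the same 4185 receptor fragments, the G9a het library had an effective number of 534 against 33.8 in the dKO, which argues against fewer sequenced fragments as the whole cause. In those draws the 5 highest receptors of G9a het held at most 4.40% of fragments, against 45.5% in the dKO, which argues against every receptor being lower alike, since that would keep their shares. Receptors with another at 95% identity or more held 4.68% of the dKO's Olfr FPKM and 17.8% of that of G9a het. This argues against reads shared between near-identical receptors. Shorter stretches shared between less similar receptors were not measured. The genotype, a small number of neurons sampled and the sex of the animal stay open and were not tested. The same holds for the part of the epithelium sampled, its age of maturation and other tissue taken along. It also holds for few RNA molecules behind the fragments, which drawing down cannot show. A hypothesis that the genotype narrows receptor choice may be examined with replicate animals of 1 sex.

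The second pattern was that receptors higher in the dKO library lie near each other. Of 100000 random sets of receptors, a share of 0.00659 held at least as many pairs within 1 Mb as the 84 observed. That share argues against chance placement only weakly, since the neighbours had been noticed first and it was the lowest of 4 comparisons. The sets were drawn from receptors at 0.5 FPKM or more in either library. Some receptors, such as Olfr444, entered through their dKO value alone, so the pool was tied to the difference itself. Without receptors that have another at 90% identity or more, the share was 0.0192, with 44 pairs against a mean of 25.3. The same limits apply, so this argues against reads shared between similar neighbours only weakly. The share was 0.188 for receptors higher in G9a KO, 0.317 in G9a KO GLP het and 0.408 in the Suv420h dKO; the difference between comparisons was not tested. A zone of the epithelium sampled more heavily and an effect of the genotype were not tested and stay open.

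The third pattern was the lower muscle genes of the Suv420h dKO library. Of the 14 measured members, 92.9% were 2-fold lower, a share that was known when the test was written. With 1 library per genotype, muscle tissue taken along in the dhet sample and an effect of the genotype on muscle cannot be told apart, and both stay open. The 8 members at 5 FPKM or more in either library had a median of -3.48, below the central 95% of random lists (-0.51 to 0.19). All 8 passed that minimum through the dhet library only, so the filter was tied to the difference itself. The test therefore cannot decide on unstable low values.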
